A study of Mus musculus with 5 samples.

How the data were processed

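Total RNA of 5 mouse hearts was measured on Affymetrix whole-transcript arrays. Per the labels' protocols, biotinylated single-stranded DNA was made from 300 ng of total RNA with the manufacturer's kit. The deposited values are on the log2 scale and were made with RMA (robust multi-array average), per the submitters' processing notes; the version of RMA, the probe set library and the genome build are not given in the sources used here. RMA corrects background, normalizes quantiles and summarises the probes of a set by median polish. Scanner files and detection calls were not used here. The table held 41345 probes and 5 columns, which were matched to samples by their sample names, and the groups (sham, n = 2, and antagonist, n = 3) were taken from the labels.

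Probes were named from the platform annotation: 23521 probes had 1 gene symbol, 1814 had several and were not used to name a gene, and 16010 were not listed. Of the single-symbol probes, 23328 were found by Entrez Gene identifier in a RefSeq gene table of assembly GRCm38.p6, used for names only, and 0 symbols changed. No coordinates are given, since the array values carry no build. For each of 22180 symbols the probe with the highest mean over all arrays was kept (1082 symbols had more than 1 probe). The 15294 genes whose mean was at or above the 40th percentile of all probes (3.42) were tested. Many values are exactly equal between arrays, as median polish over few arrays can give: 73.9% of the tested genes had fewer than 5 different values over the 5 arrays and 922 had a single value. The prior degrees of freedom that limma estimated were 0.69, beside 3 residual degrees of freedom; among genes with 5 different values they were 3.03.

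The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Differences are antagonist minus sham on the log2 scale, with limma's moderated standard error, and folds are their powers of 2. Gene lists were fixed before the data were examined. Of 46 lists, 41 had at least 4 tested members and were tested with camera (competitive, two-sided, preset inter-gene correlation 0.01), adjusted over the 41 lists, with the estimated correlation and fry beside it. Members marked as adjusted over the list alone use the same limma p, and each list was adjusted apart from the others. In a technical list of 115 tested olfactory and vomeronasal receptor genes, 3 passed in this way (smallest limma adjusted p 0.018). Such a pass alone therefore says little. Exact permutation tests ran over the 10 divisions of the 5 arrays into 2 and 3, so the smallest possible p is 0.10. The design was that planned before the data were examined.

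The named genes follow a rule fixed before the data were examined. It takes the 10 genes per direction with the largest difference past the threshold, filled up with the genes of smallest unadjusted p whose groups do not overlap. It adds all members of both clock lists and Cdkn1a, the 4 members of smallest p of each list past the threshold and of 6 further biology lists, and the 2 brightest members of each cell type list. Predicted genes are not named. Genes given per array in the account of differences between arrays, and those in the closing observations, were chosen after their values were seen. Per2 has no probe with its symbol alone and was not analysed here.

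The scripts were tested on simulated data made from the means and spreads of the 15294 genes, with 200 genes altered by known amounts in each of 20 runs. The test recovered 48.5%, 78.4% and 96.5% of changes of 0.5, 1 and 2 on the log2 scale, with 7.95 wrong calls among 156.7 calls per run. A list of 30 genes shifted by 0.2 was called in 100% of the runs with the preset correlation and in 10% with an estimated correlation, and 0 of the 41 unshifted lists were called. The simulated genes were independent of one another, unlike real genes. They were drawn from normal distributions with limma's moderated variances and held no ties, so the recovery need not hold for the measured values.

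Alternatives planned before the data were examined covered the level filter (none, or the 60th percentile), a second quantile normalization, centring of each array on its median, the mean of all probes of a symbol, every probe tested without regard to its name, eBayes with a trend or robust, array weights, the replicate number as a block, and leaving out each array in turn. For lists they also covered the estimated correlation, fry and a rank version of camera. Restricting the test to genes with differing values was chosen after seeing the data. Lists of mitochondrial, erythroid, histone, Y-linked and X-inactivation genes had too few tested members.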

Results

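Hearts of wild-type C57Bl6J mice were profiled at zeitgeber time 12, counted in hours from lights on. Each heart was isolated and perfused on a Langendorff apparatus, in which the aorta is cannulated and the heart is supplied with buffer outside the body. After 20 min of stabilisation the pump was stopped for 20 min of no-flow ischemia, and flow was then restored for 20 min before the tissue was frozen. The treated group (n = 3 hearts) came from mice given an antagonist of REV-ERB alpha by the intraperitoneal route, at 10 µM as the labels give it, 4 h and 1 h before the perfusion. REV-ERB alpha is the nuclear receptor encoded by Nr1d1, a repressor within the circadian clock that acts on genes such as Arntl and Nfil3. The control group (n = 2 hearts), called sham by the labels, went through the same ischemia and reperfusion without the antagonist. The labels name neither the compound nor an injection of vehicle in the sham mice. Hearts without ischemia were not analysed here, so every value describes reperfused tissue. Each array, described as a biological replicate, gave a log2 expression value for 41345 probes. The median value per array lay between 3.92 and 3.95, and the number of arrays limits the precision of every comparison.

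The arrays differed from one another in ways that cut across the groups. Antagonist replicate 2 carried high levels of genes of the atrium, of fat and of the mesothelium, and of several endothelial adhesion genes. Bmp10, a growth factor of atrial muscle, measured 10.9 on that array and between 3.42 and 5.88 on the other 4 arrays. The atrial genes Sln (10.4, against at most 7.66) and Myl7 (9.54, against at most 7.01) behaved alike, while the atrial light chain gene Myl4 did not (6.89, within 6.58 to 7.01). The brown fat gene Ucp1 (6.49, against at most 3.47), the fat cell genes Cidec (7.03, against at most 4.75) and Retn (7.65, against at most 5.31), and the endothelial adhesion gene Sele (8.32, against at most 5.83) were also highest there. The median excess of antagonist replicate 2 over the mean of the other arrays was 0.65 for the 15 atrial markers, 1.08 for the 10 adipocyte markers and 0.42 for the 14 mesothelial markers, against 0.02 for the 20 endothelial markers and -0.02 for the 26 sarcomere and calcium-handling genes. Sham replicate 1 stood apart more broadly. It was counted as the array farthest from the mean of the others for 6073 of 15294 genes, compared with at most 2848 for any other array. Ties in that count went to the earliest array, so the 6073 include the 922 genes with the same value on all 5 arrays and are too high. Sham replicate 1 lay at -20.6 on the first principal component, which held 43.4% of the variance. On it sham replicate 2 lay at 0.22 and the antagonist arrays between 1.59 and 14.0. Pearson correlations across probes within an array pair ranged from 0.986 to 0.990, and the sham pair was at the lower end. The Y-linked gene Eif2s3y lay between 7.49 and 7.83 and Xist between 2.37 and 2.57 on all 5 arrays.

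**Figure D1:**
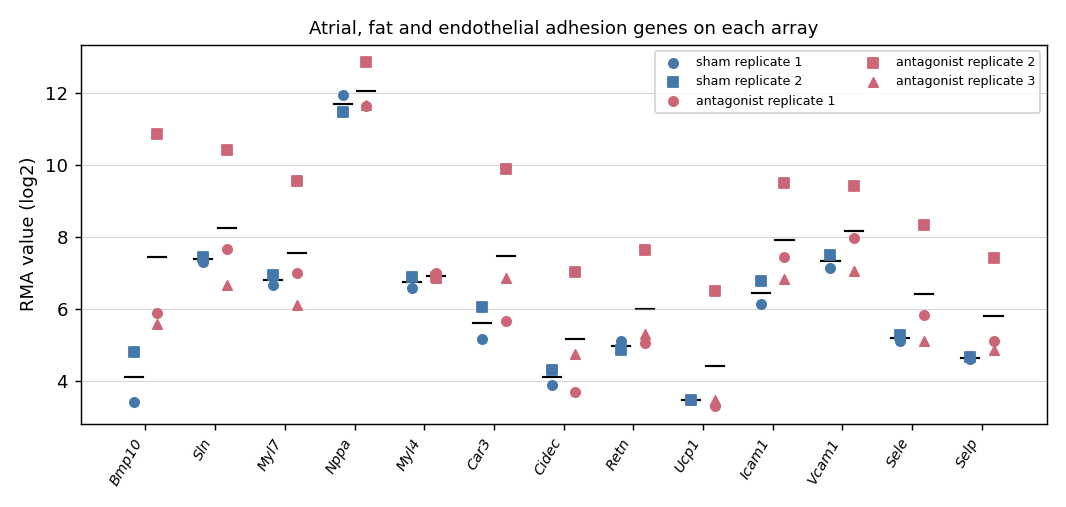
RMA values (log2, vertical axis) of atrial genes (Bmp10 to Myl4), fat genes (Car3 to Ucp1) and endothelial adhesion genes (Icam1 to Selp) on each of the 5 arrays. Blue points are sham hearts, red points antagonist hearts, the marker shape gives the replicate and black bars are group means; antagonist replicate 2 is the highest array for every gene shown except Myl4.

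The comparison of antagonist with sham hearts asks which transcripts differ after ischemia and reperfusion when REV-ERB alpha is blocked beforehand. As groups, inflammatory, glucocorticoid-responsive, unfolded protein response, hypoxia and heat shock genes were higher in the antagonist hearts, and clock output and proliferation genes were lower, at camera's preset correlation. These calls did not hold with a correlation estimated from the arrays (smallest adjusted p = 0.45 with an estimated correlation). No single gene passed: 0 of 15294 genes reached an adjusted p under 0.05 with limma, and the smallest adjusted p was 0.60. At an unadjusted p under 0.05 there were 704 genes, 341 higher and 363 lower, where 764.7 would be expected by chance. The other 9 divisions of the 5 arrays into 2 and 3 also lay below 764.7, with 197 to 524 genes. With 10 divisions in all, no share under 0.05 can be reached. Under 0.01 there were 197, where 152.9 would be expected, and among the 3991 genes with 5 different values, a restriction chosen after seeing the data, 412 were under 0.05, where 199.6 would be expected. The groups did not overlap for 1914 genes, or 12.5%, in a table where many values are tied and a tie between the groups rules out such a gap. Among the same 3991 genes without ties the groups did not overlap for 1237, or 31.0%, where chance gives 20% on average over the 10 divisions. These genes share the same 5 arrays, so a single division can lie above 20%. Neither the 412 nor the 31.0% was computed for the other divisions, so the excess cannot be judged. On simulated data with limma's moderated variances but no ties, the same test recovered 78.4% of changes of 1 on the log2 scale among 200 altered genes. For changes of 0.5 it recovered 48.5%, and recovery on the tied values of these arrays may differ. Of 18 genes with a difference of at least 1 on the log2 scale, 17 had their highest value on antagonist replicate 2. Leaving out sham replicate 1 turned the 0 calls into 1319 and leaving out sham replicate 2 into 2058, where a single sham array is set against antagonist values that are often exactly equal: 92.6% and 78.6% of those genes had tied values on antagonist arrays, compared with 53.1% of the genes tested.

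The genes of smallest unadjusted p whose groups did not overlap had little spread within the groups, and none passed the adjustment. For Fgf11, Hey2 and Isca2 the values on all antagonist arrays were exactly equal, and for Urad, Tmem9, Bmyc and Olfr1269 some were. The small SE of these genes comes with tied values and need not measure the spread between hearts. Among those higher with the antagonist were Map3k14, the NF-kB-inducing kinase (log2 difference 0.35 ± 0.02, SE), Xdh, which makes xanthine oxidoreductase (0.50 ± 0.04), Slc3a2, the heavy chain of amino acid transporters (0.25 ± 0.03), and Chchd7 (0.25 ± 0.02). Fgf11, Urad, Mapkbp1 and Rbm38 differed by 0.11 to 0.22, while other probes gave -0.10 for Mapkbp1 and -0.11 to 0.06 for Rbm38. The olfactory receptor genes Olfr535 (3.80 in sham and 4.80 with the antagonist) and Olfr1269 (4.09 and 4.40) completed the 10. Of these means only that of Olfr535 in sham lay below the array medians of 3.92 to 3.95, and the level filter was 3.42. Lower with the antagonist were the transcription factor Nfic (-0.34 ± 0.02), the small-conductance potassium channel gene Kcnn2 (-0.42 ± 0.04), the ventricular Notch target Hey2 (-0.22 ± 0.02), the collagen gene Col8a1 (-0.21 ± 0.02) and the efflux pump gene Abcb1a (-0.18 ± 0.02). Zfp959 (-0.46), Bmyc (-0.31, with a second probe at -0.04), Vmn2r58 (-0.25), Tmem9 (-0.14) and Isca2 (-0.12) were the other 5.

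Of 41 gene lists tested, 14 passed an adjusted p under 0.05 with limma's camera at its preset correlation, 12 of them higher and 2 lower in the antagonist hearts. With a correlation estimated from the arrays 0 of the 14 passed (smallest adjusted p 0.45), so each list below carries its value under an estimated correlation. With fry 0 of the 41 lists passed. The smallest fry adjusted p was 0.061, for fetal and stress genes of heart muscle, a list that is not among the 14. Among the 14 the smallest fry adjusted p was 0.081. A different division of the same arrays, antagonist replicates 1 and 2 against the rest, also gave 14 lists, and antagonist replicates 1 and 3 against the rest gave 13. Without antagonist replicate 2, 10 of the 14 passed, without sham replicate 1 only 5 and without sham replicate 2 only 4.

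**Figure D2:**
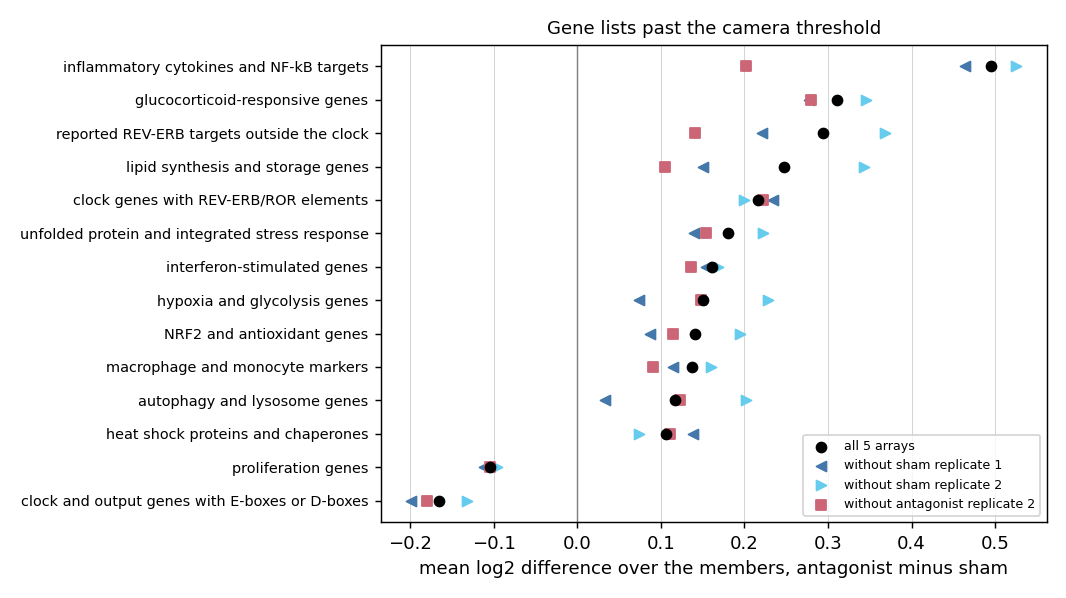
Mean log2 difference (antagonist minus sham, horizontal axis) over the measured members of each of the 14 lists past the camera threshold. Black circles use all 5 arrays, triangles leave out a sham array and red squares leave out antagonist replicate 2; without that array the inflammatory list moves from 0.49 to 0.20 and the proliferation list stays at -0.10.

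Cdkn1a (Entrez Gene 12575), which encodes the cyclin-dependent kinase inhibitor p21, was higher in each antagonist heart than in either sham heart. Its value was 7.91 ± 0.11 (SD, n = 3) with the antagonist and 7.17 ± 0.16 (SD, n = 2) in sham, a log2 difference of 0.74 ± 0.11 (SE) or 1.67-fold. The limma adjusted p over all genes was 0.64. In the exact two-sided permutation test over the 10 divisions of the 5 arrays the p was 0.10, the smallest this design allows. The 25 other measured p53 targets and CDK inhibitors went both ways, 13 higher and 11 lower with a mean difference of 0.02, and the list of 26 with Cdkn1a did not pass (camera adjusted p = 0.52). Adjusted over the list alone, 0 members passed.

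Clock genes differed in opposite directions. All 11 measured clock and output genes that carry E-boxes or D-boxes were lower in the antagonist hearts, with a mean log2 difference of -0.16 (camera adjusted p = 0.0013; adjusted p = 0.45 with an estimated correlation). The largest were Dbp, a D-box activator (-0.50 ± 0.14, SE), and Bhlhe41, a repressor of E-box genes (-0.38 ± 0.13), followed by Nr1d1 itself (-0.28 ± 0.23), Per3 (-0.20 ± 0.06) and Ciart (-0.15 ± 0.09). Bhlhe40 (-0.09), Tef (-0.07, with a second probe at 0.02), Per1 (-0.06), Hlf (-0.04), Nr1d2 (-0.03) and Cry2 (-0.0015) differed by less, and the sign for Cry2 changed when single arrays were left out. With single arrays left out 10 or 11 of the 11 stayed lower, but several came near 0: Nr1d1 was at -0.11 without antagonist replicate 3, Per1 at -0.01 without antagonist replicate 1, Ciart at -0.05, Hlf at -0.0049 and Tef at -0.0025 without sham replicate 2, and Bhlhe40 at -0.01 and Nr1d2 at -0.0017 without sham replicate 1. The 5 clock genes with binding elements for REV-ERB and ROR receptors were higher on average by 0.22 (camera adjusted p = 0.049; adjusted p = 0.54 with an estimated correlation). In this list Nfil3, a D-box repressor, measured 6.57 ± 0.12 (SD, n = 3) with the antagonist and 5.90 ± 0.01 (SD, n = 2) in sham, or 1.59-fold. Arntl, which encodes the activator BMAL1, differed by 0.33 ± 0.13 (SE), or 0.15 without sham replicate 1, and Cry1 by 0.07 ± 0.06, or 0.02 without antagonist replicate 1, while Clock (0.01 ± 0.19) and Npas2 (0, with the same value on every array) did not differ. Nfil3 was the 1 gene that passed when limma's p was adjusted over the list alone, for both clock lists together (adjusted p = 0.027); over all genes its adjusted p was 0.62. That call ended without sham replicate 1, antagonist replicate 2 or antagonist replicate 3. The call of the E-box and D-box list ended without sham replicate 2 (adjusted p = 0.23), and that of the REV-ERB and ROR element list without sham replicate 1 (0.17), sham replicate 2 (0.67), antagonist replicate 2 (0.058) or antagonist replicate 3 (0.070). The latter call also ended with the 60th percentile level filter (adjusted p = 0.054), with array weights (0.082) and on ranks (0.15).

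**Figure D3:**
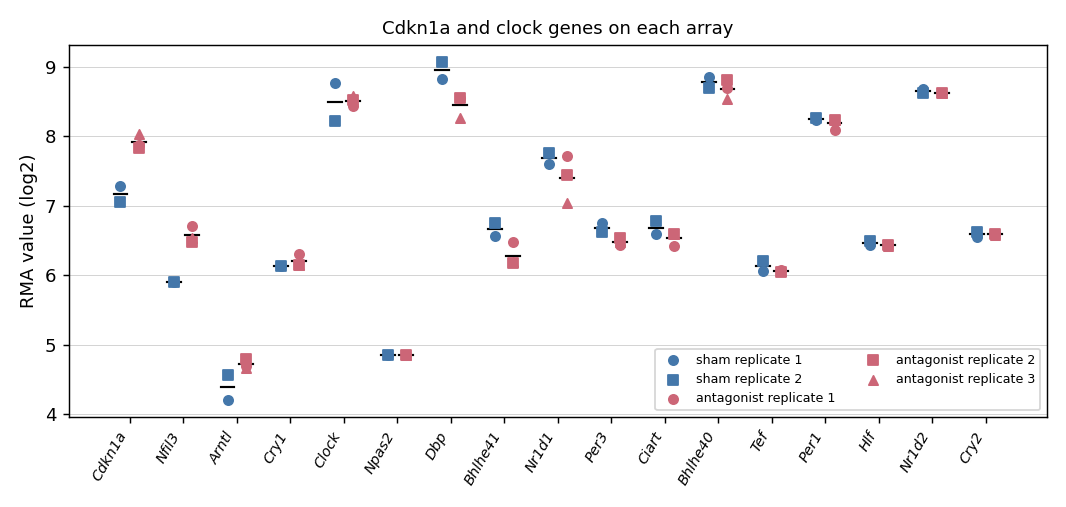
RMA values (log2, vertical axis) of Cdkn1a and the 16 measured clock genes on each array. Blue points are sham hearts, red points antagonist hearts, the marker shape gives the replicate and black bars are group means; Cdkn1a, Nfil3, Arntl and Cry1 lie higher on every antagonist array than on either sham array, and Dbp, Bhlhe41 and Per3 lie lower.

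Genes that respond to glucocorticoids were higher in the antagonist hearts, in 20 of 24 measured members, by a mean of 0.31 on the log2 scale (camera adjusted p = 2.9e-05). With an estimated correlation the adjusted p was 0.45. Fkbp5, a co-chaperone of the glucocorticoid receptor, was 1.90-fold higher (0.93 ± 0.11, SE), the metallothionein gene Mt2 1.44-fold (0.52 ± 0.08) and the zinc finger gene Zbtb16 1.43-fold (0.51 ± 0.08), and Cdkn1a also belongs to this list. These 4 passed when limma's p was adjusted over the list alone (smallest adjusted p 0.028), as 3 olfactory and vomeronasal receptor genes did in theirs. Of these 4, 0 passed over all genes. The list kept its call without antagonist replicate 2 (mean 0.28) and lost it without sham replicate 1 (adjusted p = 0.17).

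Genes of the unfolded protein and integrated stress response, and heat shock and chaperone genes, were higher as groups at camera's preset correlation. Of 21 measured genes of the unfolded protein and integrated stress response, 20 were higher, by a mean of 0.18 (camera adjusted p = 3.3e-05; adjusted p = 0.45 with an estimated correlation). Herpud1, of the degradation machinery of the endoplasmic reticulum, differed by 0.49 ± 0.09 (SE), the chaperone genes Creld2 by 0.47 ± 0.13 and Hyou1 by 0.31 ± 0.08, and Hspa5, which encodes BiP, by 0.22 ± 0.04. In the heat shock list 16 of 19 members were higher, by a mean of 0.11 (camera adjusted p = 5.8e-04; adjusted p = 0.52 with an estimated correlation). Hsph1 differed by 0.46 ± 0.10, Ahsa1 by 0.33 ± 0.11, Hspa8 by 0.17 ± 0.02 and Cryab by 0.13 ± 0.04. The other probes of Hspa8 gave 0.46 to 0.66, and a second probe of Cryab gave 0.20. Adjusted over the list alone, Hspa8 passed (limma adjusted p = 0.031) and 0 members of the unfolded protein list did. Antioxidant genes regulated by NRF2 were higher in 16 of 20 members, by a mean of 0.14 (camera adjusted p = 0.019; adjusted p = 0.60 with an estimated correlation). Mt2 led this list too, with the thioredoxin reductase gene Txnrd1 at 0.36 ± 0.11, Sqstm1 at 0.39 ± 0.19 and Mt1 at 0.16 ± 0.06, and 0 members passed adjusted over the list alone. Without sham replicate 2 the unfolded protein list (adjusted p = 0.067) and the heat shock list (0.23) lost their calls, and the NRF2 list lost its call without either sham array (0.25 and 0.052) or without antagonist replicate 1 (0.073) or 2 (0.064). Without sham replicate 1 the mean of the NRF2 list was 0.09, with Txnrd1 at 0.23 and Sqstm1 at 0.11, and in the heat shock list Ahsa1 was at 0.20 and Cryab at 0.07; Mt1 was at 0.07 without sham replicate 2.

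**Figure D4:**
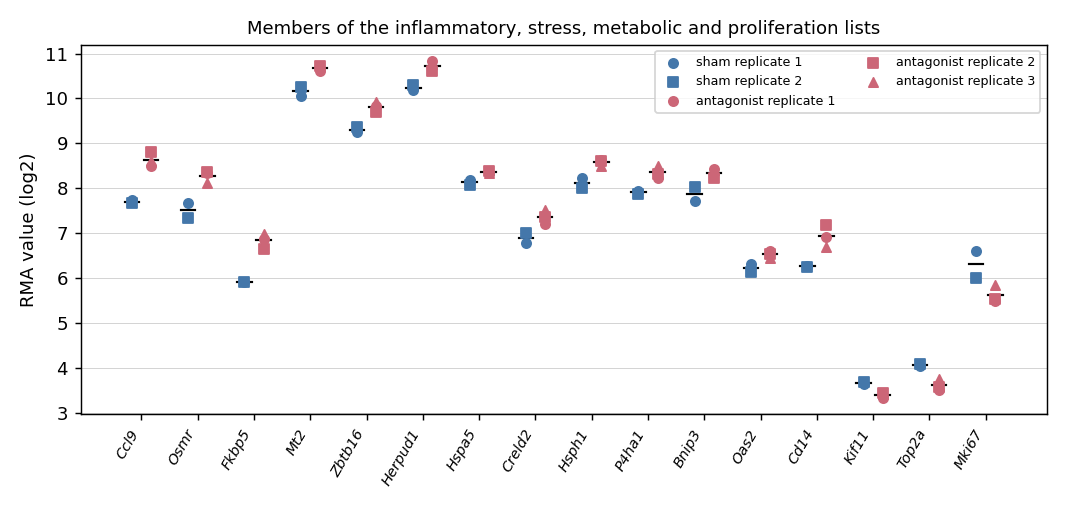
RMA values (log2, vertical axis) of members of the inflammatory (Ccl9, Osmr), glucocorticoid-responsive (Fkbp5, Mt2, Zbtb16), unfolded protein (Herpud1, Hspa5, Creld2), heat shock (Hsph1), hypoxia (P4ha1, Bnip3), interferon (Oas2), macrophage (Cd14) and proliferation (Kif11, Top2a, Mki67) lists on each array. Blue points are sham hearts, red points antagonist hearts, the marker shape gives the replicate and black bars are group means. None of the 16 genes overlaps between the groups, but they were picked from the members of smallest p of their lists. In the whole lists 12 of 32 inflammatory, 4 of 24 interferon and 5 of 27 proliferation members did not overlap, beside 12.5% of all genes tested.

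Inflammatory cytokine genes and targets of NF-kB showed the largest list difference that passed, a mean of 0.49 with 31 of 32 measured members higher (camera adjusted p = 2.9e-05). With an estimated correlation the adjusted p was 0.73. The rank rested on antagonist replicate 2: without it the mean was 0.20 for this list and 0.28 for the glucocorticoid-responsive list. The chemokine gene Ccl9 was 1.91-fold higher (0.94 ± 0.11, SE) and Osmr, the oncostatin M receptor gene, 1.70-fold (0.77 ± 0.14). Il1b differed by 0.74 ± 0.33 and the receptor gene Tlr2 by 0.31 ± 0.14. Adjusted over the list alone, Ccl9 passed (limma adjusted p = 0.042). Antagonist replicate 2, the array with the high atrial, fat and adhesion genes, had the highest value of 28 of the 32 members; without it the mean difference was 0.20 (adjusted p = 7.1e-04), with Il1b at 0.49 and Tlr2 at 0.19, and without sham replicate 2 the call ended (adjusted p = 0.092). Interferon-stimulated genes were higher in 21 of 24 members, by a mean of 0.16 (camera adjusted p = 0.0052; adjusted p = 0.72 with an estimated correlation). Oas2, an antiviral enzyme gene, differed by 0.30 ± 0.08, and the interferon signalling genes Stat2, Irf9 and Ddx58 by 0.48 ± 0.17, 0.32 ± 0.15 and 0.10 ± 0.05. No interferon gene passed when adjusted over the list alone. The interferon call ended without sham replicate 1 (adjusted p = 0.22), where Stat2 differed by 0.27, Irf9 by 0.15 and Ddx58 by 0.07, and without sham replicate 2 (0.25).

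Macrophage and monocyte markers were higher by a mean of 0.14, in 14 of 22 members with 7 lower (camera adjusted p = 0.033). With an estimated correlation the adjusted p was 0.60. Cd14, a receptor for bacterial lipopolysaccharide, differed by 0.67 ± 0.17 (SE), the Fc receptor gene Fcgr1 by 0.34 ± 0.06, the protease gene Ctss by 0.26 ± 0.06 and the class II antigen genes H2-Eb1 and H2-Ab1 by 0.36 ± 0.14 and 0.39 ± 0.26. The abundant lysozyme gene Lyz2 differed by 0.09 ± 0.10. Reported targets of REV-ERB outside the clock were higher in 15 of 17 members, by a mean of 0.29 (camera adjusted p = 0.013; adjusted p = 0.45 with an estimated correlation). Their members of smallest p were Bnip3 (0.47 ± 0.13), a mitophagy receptor gene, Il1b, the inflammasome gene Nlrp3 (0.55 ± 0.27) and Lpl, the lipoprotein lipase gene (0.08 ± 0.04, with a second probe at 0.24). Il6, Il1b, Ccl2 and Nlrp3 are also in the inflammatory list and Bnip3 in the hypoxia and autophagy lists, so these calls are not independent. In neither the macrophage list nor the list of REV-ERB targets did a member pass when adjusted over the list alone. The macrophage call ended without sham replicate 1 (adjusted p = 0.099), sham replicate 2 (0.78) or antagonist replicate 2 (0.096, mean 0.09), with array weights (0.085) and on ranks (0.064). The call of the REV-ERB targets ended without sham replicate 1 (0.17) or 2 (0.23), and its mean was 0.14 without antagonist replicate 2 (adjusted p = 0.046). Without sham replicate 1 H2-Ab1 differed by 0.14, Nlrp3 by 0.18 and Lyz2 by 0.03, without antagonist replicate 2 Lyz2 differed by 0.03, and without antagonist replicate 3 Lpl differed by 0.05.

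Hypoxia and glycolysis genes were higher in 23 of 24 members, by a mean of 0.15 (camera adjusted p = 2.5e-04; adjusted p = 0.60 with an estimated correlation). P4ha1, a prolyl hydroxylase subunit gene induced in hypoxia, differed by 0.44 ± 0.09 (SE), Bnip3 by 0.47 ± 0.13, and the glycolysis genes Pgam1 and Pfkfb2 by 0.31 ± 0.05 and 0.29 ± 0.11, though a second probe of Pgam1 gave -0.26. Autophagy and lysosome genes were higher in 25 of 31 members, by a mean of 0.12 (camera adjusted p = 0.0030; adjusted p = 0.72 with an estimated correlation). Map1lc3b, whose product coats autophagosomes, differed by 0.31 ± 0.12, the cargo receptor gene Sqstm1 by 0.39 ± 0.19 and Atg5 by 0.19 ± 0.09. Lipid synthesis and storage genes were higher in 19 of 23 members, by a mean of 0.25 (camera adjusted p = 0.017; adjusted p = 0.73 with an estimated correlation). Here Lpin1 differed by 0.41 ± 0.13, Plin4, a lipid droplet coat gene, by 0.47 ± 0.17, Dgat1, of triglyceride synthesis, by 0.31 ± 0.12 and the lipase gene Pnpla2 by 0.10 ± 0.05. Adjusted over the list alone, 0 members of these 3 lists passed. Fat cell genes were high on antagonist replicate 2, and without it the lipid list had a mean of 0.11 and lost its call (adjusted p = 0.28). Without sham replicate 1 the means were 0.07 for hypoxia (adjusted p = 0.46), 0.03 for autophagy (0.37) and 0.15 for lipid genes (0.87), and all 3 calls ended. Sqstm1 then differed by 0.11, Map1lc3b by 0.18, Lpin1 by 0.23, Plin4 by 0.22 and Pnpla2 by 0.04, and Atg5 by 0.08 without sham replicate 2.

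Proliferation genes were lower in the antagonist hearts, in 20 of 27 measured members with 3 higher, by a mean of -0.10 (camera adjusted p = 0.0023). With an estimated correlation the adjusted p was 0.45. Mki67, which encodes the proliferation antigen Ki-67, differed by -0.68 ± 0.24 (SE), the topoisomerase gene Top2a by -0.44 ± 0.09, the mitotic kinesin gene Kif11 by -0.27 ± 0.04 and the spindle gene Nusap1 by -0.20 ± 0.09. Their levels were low: Kif11, Top2a and Nusap1 had group means between 3.40 and 4.06, near the level filter of 3.42. Mki67 differed by -0.38 without sham replicate 1 and Nusap1 by -0.07 without sham replicate 2. Adjusted over the list alone, 0 members passed, and the call ended without sham replicate 2 (adjusted p = 0.15) and with the stricter level filter at the 60th percentile (0.18).

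The remaining lists did not pass. Apoptosis regulators differed by a mean of 0.06 (camera adjusted p = 0.16); Birc2, an inhibitor of apoptosis, differed by 0.20 ± 0.02 (SE) and passed when adjusted over the list alone (limma adjusted p = 0.049), and Bcl2l1 and Cflar differed by 0.32 ± 0.13 and 0.19 ± 0.08, the latter by 0.11 without sham replicate 1. Fetal and stress genes of heart muscle, among them the atrial genes Nppa and Myl7, differed by 0.15 (camera adjusted p = 0.17) and by 0.06 without antagonist replicate 2, with the natriuretic peptide gene Nppb at 0.37 ± 0.10, Flnc at 0.19, Timp1 at 0.06 and Ankrd2 at -0.09; without sham replicate 1 Flnc was at 0.06, Timp1 at 0.01 and Ankrd2 at -0.03. Proteasome subunits differed by 0.03 (0.28), with Psmc6 at -0.15 ± 0.02, Psme1 at -0.28, Psmc2 at 0.25 and Psma5 at 0.13. Second probes gave 0.07 for Psmc2 and -0.43 for Psma5. The proteasome subunits passed without antagonist replicate 2 (0.014). Their mean was -0.01 without sham replicate 1, where Psmc2 was at 0.09, and 0.08 without sham replicate 2, where Psme1 was at -0.11. Fatty acid oxidation and PPAR target genes differed by 0.07 (0.28), with Pdk4, a brake on glucose oxidation, at 0.38 ± 0.12, Mlycd at 0.31, Cd36 at 0.08 and Acot2 at -0.16, of which Pdk4 was at 0.22, Mlycd at 0.14 and Acot2 at -0.06 without sham replicate 1. Cholesterol synthesis genes differed by -0.01 (0.38), with Fdft1 at -0.07, Dhcr7 at -0.12, Mvk at -0.14 and Hsd17b7 at -0.21; without sham replicate 1 Mvk was at -0.03, and without sham replicate 2 Hsd17b7 was at -0.03 and the mean at 0.04. Ion channel and conduction genes differed by -0.03 (0.38); Gja1, the connexin gene of ventricular gap junctions, differed by -0.42 ± 0.09, Kcnd2 by -0.27 ± 0.09, Cacnb2 by -0.09 (-0.05 without antagonist replicate 1, and 0.08 for a second probe) and Klf15 by 0.29 (0.18 without antagonist replicate 3). Cytosolic ribosomal proteins (0.18) and respiratory chain subunits (0.38, but 0.036 without sham replicate 2) did not pass, nor did immediate-early genes (0.89), whose test pointed lower while their mean (0.04) and median (0.02) were above 0.

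Markers of the cell types of the heart gave no further call with all arrays, but some calls appeared in other settings. Sarcomere and calcium-handling genes had a mean of 0.04 (camera adjusted p = 0.29) and passed without antagonist replicate 2 (0.046) and after a second quantile normalization (0.040), with Tnnt2 at -0.01 ± 0.02 (SE), which turned to 0.03 after that normalization, and Atp2a2 at 0.12 ± 0.05, or 0.05 without sham replicate 1. Endothelial markers, 13 of 20 higher with a mean of 0.05 (camera adjusted p = 0.38) that was -0.02 without sham replicate 1, held Cdh5 at -0.23 ± 0.05 and Fabp4 at -0.03 ± 0.05. Fibroblast markers (0.16) held Gsn at 0.38 ± 0.39 and Dcn at -0.01 ± 0.09. Their mean was -0.21 without sham replicate 1, and they passed as lower without antagonist replicate 2 (mean -0.12, adjusted p = 0.027). Smooth muscle markers (0.38) held Rgs5 at -0.22 ± 0.13, or -0.02 without sham replicate 1 and -0.10 for a second probe, and Des at -0.01 ± 0.01. Atrial markers had a mean of 0.50 (0.17), with Nppa at 0.36 ± 0.49 and Pam at 0.30 ± 0.24, and that mean was 0.05 without antagonist replicate 2, with Nppa at -0.04 and Pam at 0.10, and 0.79, past the threshold (0.011), without antagonist replicate 3. Adipocyte markers had a mean of 0.60 (0.18), with Car3 at 1.85 (1.09 for a second probe) and Cidea at 0.26 ± 0.13. Without antagonist replicate 2 the adipocyte mean was 0.11, with Car3 at 0.64 and Cidea at 0.15. Mesothelial markers, which passed without antagonist replicate 1 (0.019), had a mean of 0.19 (0.16), with Gpm6a at 0.34 ± 0.57 and Efemp1 at 0.16 ± 0.42. Without antagonist replicate 2 the mesothelial mean was -0.02, with Gpm6a at -0.15 and Efemp1 at -0.19. Neutrophil markers (0.38) held Lcn2 at 0.49 ± 0.26 and Hdc at -0.10 ± 0.06, or 0.11 and -0.01 without sham replicate 2. The B cell list (0.40) held Ighm at 0.24 ± 0.32, or 0.0021 without antagonist replicate 2 and with other probes at -0.35 to 0.26, and Bank1 at -0.21 ± 0.06, or -0.13 without sham replicate 1, and its test pointed lower, as its median of -0.04 did, while its mean was 0.0064. T cell (0.62), thymus (0.67), lung (0.35), skeletal muscle (0.38) and nerve markers (0.89) did not pass either, and their brightest members, Cd28, Cd8b1, Satb1, Ptcra, Ager, Sftpc, Mybpc2, Tnnc2, Pmp22 and Erbb3, differed by -0.26 (Erbb3, -0.06 without sham replicate 2) to 0.23 (Ager, 0.04 without antagonist replicate 3). The nerve test pointed higher while the mean of its members was -0.02.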

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

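With limma, 0 genes passed the adjusted threshold in the main analysis and under every alternative that kept both sham arrays, including every probe tested and the restrictions to genes with differing values, which were chosen after seeing the data. Leaving out single arrays gave 0 to 2058 genes past the adjusted threshold; the calls appeared only with 1 sham array, assumed to vary like the antagonist arrays, and mostly among genes with tied antagonist values. At an unadjusted p under 0.05 the main count of 704 became 318 with array weights, 1245 (genes at unadjusted p under 0.05, antagonist against sham) with every probe tested, 412 among the 3991 genes with 5 different values (chosen after seeing the data), where 199.6 would be expected by chance against 764.7 in the main analysis, and 539 to 4041 with single arrays left out. The 14 list calls became 0 with an estimated correlation, 0 with fry, and 5 to 15 with single arrays left out; the other settings gave 12 to 17. Clock genes past the list-wise adjustment (1, Nfil3) became 0 with array weights and lay between 0 and 1 with arrays left out. Cdkn1a kept its direction in all settings, with log2 differences from 0.62 to 0.86. Apart from the settings named here, the cause of a change was not tested. The 412 was not counted for other divisions of the arrays, so its excess over 199.6 cannot be judged.

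Replicate numbers 1 and 2 occur in both groups, and the correlations of same-numbered deviations were -0.11 and 0.03. With 2 sham arrays the sham deviations mirror each other, so these values cannot settle whether the numbers pair the samples. With the replicate block, 0 genes passed, 754 had an unadjusted p under 0.05, 17 lists passed, 0 clock genes passed and Cdkn1a differed by 0.68. Under it small differences turned for Clock (-0.024), Cry2 (0.0045) and Dcn (0.057), and the direction of the list test, though not of the mean, turned for nerve and Schwann cell markers (mean -0.0020) and immediate-early genes (0.12, past the threshold with adjusted p = 0.046). The call of the clock genes with REV-ERB/ROR elements ended (adjusted p = 0.093), and calls appeared for atrial (0.013) and mesothelial markers (0.026).

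The other genes and lists that turned had not passed in the main analysis, except the lipid synthesis list, whose test turned without sham replicate 1 (adjusted p = 0.87). A second quantile normalization gave -0.0070 for Clock, 0.029 for Tnnt2 and 0.034 for immediate-early genes. Centring on array medians gave -0.020 for nerve and Schwann cell markers and 0.043 for immediate-early genes. Without the level filter the lung and airway epithelium markers had a mean of -0.0016 and the B cell markers 0.041; with the 60th percentile filter the nerve list had -0.097, and fry put its direction (mean -0.018) lower.

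With single arrays left out, differences spanned 0 for Clock (-0.27 to 0.28), Cry2 (-0.039 to 0.037), Dcn (-0.075 to 0.057), Des (-0.011 to 0.0014), Fabp4 (-0.056 to 0.0040), Gsn (-0.17 to 0.92), Efemp1 (-0.19 to 0.39), Gpm6a (-0.15 to 0.64), Nppa (-0.044 to 0.59), Mybpc2 (-0.11 to 0.042), Cd28 (-0.16 to 0.049) and Pmp22 (-0.030 to 0.027). List means whose test direction turned ranged from 0.11 to 0.34 for lipid synthesis, 0.022 to 0.092 for apoptosis, -0.21 to 0.074 for fibroblast, -0.016 to 0.29 for mesothelial, 0.047 to 0.79 for atrial, -0.030 to 0.17 for fatty acid oxidation, -0.013 to 0.099 for sarcomere, 0.027 to 0.10 for skeletal muscle, -0.074 to 0.024 for ion channel, -0.043 to 0.10 for respiratory chain, -0.063 to 0.076 for B cell, -0.041 to -0.022 for T cell, -0.048 to 0.012 for nerve and -0.028 to 0.12 for immediate-early genes. The mean but not the test direction spanned 0 for proteasome (-0.014 to 0.080), cholesterol synthesis (-0.058 to 0.037), endothelial (-0.023 to 0.13) and neutrophil lists (-0.0011 to 0.12). Among the named genes, 1157 of the values under other settings and 593 of those with an array left out kept direction and side of the threshold, while 5 of the former and 17 of the latter turned and 45 of the latter gained a call. The number of arrays, and signals near the level filter for genes such as Kif11, limit what can be seen.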

Other observations

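The tests of explanations in this part, and the bounds they were held against, were chosen after the values had been seen. The fit of the gene lists without antagonist replicate 2 and the divisions of the arrays for the count of single genes were planned before the data were examined.

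Several genes not named so far, chosen here after their values were seen, differed between the groups without resting on antagonist replicate 2 alone. Ccl6, a chemokine gene of myeloid cells, had a log2 difference of 1.32 ± 0.19 (SE). The C-type lectin genes Clec4d (1.01 ± 0.14, and 0.92 without that array) and Clec4e (1.10 ± 0.40, and 0.82), the acute-phase gene Serpina3n (1.02 ± 0.17, and 0.94) and the chemokine gene Ccl12 (1.03 ± 0.37, and 0.75) were also higher on all 3 antagonist arrays than on both sham arrays. Depp1, a gene induced by FOXO factors, differed by 0.73 ± 0.10. The kinase gene Map3k6 differed by 0.78 ± 0.18 and is already counted as a member of the glucocorticoid-responsive list. The apelin receptor gene Aplnr was lower on every antagonist array (-0.60 ± 0.16). None of these passed the adjusted threshold (limma adjusted p = 0.64 for each).

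Other genes with large differences followed antagonist replicate 2. Hp, an acute-phase gene also made by fat, had a difference of 1.35 over all arrays and 0.20 without that array, Cyp2e1 1.31 and 0.20, Lgals12 1.17 and 0.37, and Scd1 1.56 and 0.57. Bmp10 and the B cell chemokine gene Cxcl13 were different: without that array they still differed by 1.61 and 1.52.

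On antagonist replicate 2, which carried atrial and fat genes at high levels, the fixed atrial markers had a median excess of 0.65 there over the mean of the other arrays, where no other array exceeded -0.15, and the fixed adipocyte markers 1.08, where no other array exceeded -5.1e-04. Mesothelial markers were also high there (0.42, other arrays at most -0.05) and endothelial markers were not (0.02). The mean set against each other array includes antagonist replicate 2, which lowers the values of those arrays. Atrial muscle and fat left on that heart are candidate sources, but these markers restate the pattern that raised the question and do not test it. Only 7 of 15 atrial and 5 of 10 adipocyte markers were more than 1 above the mean of the others. Myl4, Gja5, Nr2f1, Nr2f2, Pparg and Fabp5 were about level with it. For the same 25 markers as a set, a shared response of that size in the treated hearts is argued against. Their median difference between the other antagonist arrays and sham was 0, with an upper quartile of 0.14. Single markers varied: Bmp10 still differed by 1.61 and Car3 by 0.64, beside 0.20 for Retn and 0.12 for Cidec. For Bmp10 sham replicate 1 lay at 3.42, near the level filter, and sham replicate 2 at 4.81. Antagonist replicates 1 and 3 lay at 5.88 and 5.57. For Car3 the groups overlapped even so, with antagonist replicate 1 (5.66) below sham replicate 2 (6.06). A shared response of single genes therefore stays open. A response in that animal alone stays open.

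Inflammatory genes were higher in the antagonist hearts by a median of 0.38. That array alone cannot be told apart from a shared difference: without it the list had a mean of 0.20 and kept its call at the preset correlation but not at an estimated correlation (adjusted p = 0.68), and antagonist replicates 1 and 3 lay 0.36 and 0.04 above the sham mean, where the sham arrays lay -0.03 and 0.03 from it. More macrophages cannot be told apart either: their markers had a median difference of 0.075 with an upper quartile of 0.34, and without that array the upper quartile (0.25) lay above the inflammatory median (0.19). Injection and handling of the treated mice cannot be told apart from the compound: glucocorticoid-responsive genes had a mean difference of 0.31, and the labels do not say whether sham mice were injected. An effect of REV-ERB alpha on inflammatory genes stays open as the biological explanation and was not tested apart from these.

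The clock genes may reflect a later clock phase in the antagonist hearts. That hypothesis was taken, after the values were seen, to mean lower E-box and D-box genes and higher genes with REV-ERB and ROR elements. Whether a later phase would lower each of these E-box and D-box genes at this time of day was not tested. Of the E-box and D-box genes 11 of 11 were lower (10 or 11 with single arrays left out, several of them near 0). This count restates the pattern that prompted the hypothesis and does not test it. Release of repression by REV-ERB alpha could equally raise the genes with REV-ERB and ROR elements, which had a mean difference of 0.22. Such release cannot be told apart from a shift of phase with a single time point, since higher Nfil3 can itself lower D-box genes. Both groups were collected at the same labelled time.

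Divisions of the 5 arrays into 2 and 3 number 10, too few for a share under 0.05. The real division gave 704 genes at an unadjusted p under 0.05, and the highest of the others 524; it was the 1 division with as many. For lists the real division gave 14 and the highest of the others 14, so 2 of the 10 divisions gave as many.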
